A study of Mus musculus with 6 samples.

How the data were processed

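Total RNA of LPS-stimulated peritoneal macrophages was depleted of ribosomal RNA and made into strand-marked cDNA libraries, per the labels' protocols. Mice were 6 to 8 weeks old, received 1 mL of thioglycollate medium, and adherent cells were given medium alone or medium with 200 µM 10(Z)-hexadecenoic acid. There were 3 libraries per group, numbered 1 to 3 in both. The labels do not say whether the numbers stand for separate animals, pools or cultures, so the p-values measure the spread between these libraries, which may be partly technical.

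The deposited table holds a normalized signal per gene and library: HTSeq read counts divided by a DESeq size factor. Per the submitters' processing notes, the tools were FastQC, Trimmomatic, TopHat2, SAMtools, HTSeq and DESeq with the genome build mm10; their versions, the annotation release and the strand setting of the counting are not given in the sources used here. Every deposited value of the 38293 genes was a whole multiple of its library's smallest step within a tolerance of 0.001 (100.0% of values), so whole reads and size factors were recovered; the step of vehicle replicate 2 lies near 1, which makes its recovery less certain. The symbols come from a separate reference list joined by gene identifier, which gives 36345 genes a symbol and 1948 none. Coordinates and overlaps come from a GENCODE annotation of GRCm38, the same assembly as mm10, joined by gene identifier.

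The table ends with 5 HTSeq summary entries, which were kept out of library sizes and tests. Between 28546168 and 38098482 were recorded per library in all, of which 13.7% to 15.7% were assigned to genes, 41.4% to 45.4% fell on no feature, 40.7% to 44.1% were not unique and 0.114% to 0.153% were ambiguous. Gene reads numbered 4291779, 5042026 and 4386397 in vehicle replicates 1 to 3 and 4489698, 5963153 and 5388499 in treated replicates 1 to 3. A gene of 100 reads has a Poisson error of 10%, and a count of 0 allows up to 3 reads, counting error only; reads were not marked with molecular identifiers. The gene Lars2 took 27.3% to 30.8% of the gene reads, and all 37 genes of the mitochondrial chromosome had 0 reads. Libraries of 1 group differed by 8.52 to 18.6 times the variance expected from counting alone (chi-square over degrees of freedom), so none was treated as a duplicate.

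Differences were tested with limma 3.58.1 in R 4.3.3 on log2(normalized reads + 1), with a trended prior, two-sided, over 10999 genes with a mean of at least 10 normalized reads, and Benjamini-Hochberg adjusted p under 0.05. Fold changes are on that scale, which understates the change of low genes. The comparison and its alternatives were fixed before the data were examined: a fit without a replicate block, with the replicate number as a block as an alternative. Pairing was then checked from the values. Same-numbered libraries of both groups deviated together from their group means across genes (correlations 0.52, 0.60 and 0.26 for replicates 1, 2 and 3). Those of different number had correlations between -0.50 and -0.08. Deviations from a group mean cancel within the group, so positive same-number values force negative ones elsewhere on balance. The negative values are therefore not separate evidence. The pairing therefore comes from the titles' numbers and this check, not from a stated design. DESeq2 1.42.0 and edgeR 4.0.16 (quasi-likelihood test) were run on the recovered reads as alternatives.

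The 31 gene lists were fixed before the data were examined; 26 had at least 5 tested members. They were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Without the block 12 lists were called (1 higher, 11 lower) and with it 13. With an estimated correlation 0 were called in either fit, the smallest adjusted p being 0.202 and 0.302. The estimated form also rests on the few residual degrees of freedom of 3 libraries per group. In the block fit heat shock genes had an estimated correlation of 0.011, close to the preset 0.01. Their camera adjusted p was still 9.38e-05 with the preset and 0.302 with the estimate. A miss with the estimate is therefore not by itself evidence that inter-gene correlation made the preset call. The rotation test fry, which asks whether a list's genes move one way on balance, called 0 lists in either fit. Its mixed form, which asks whether they change in either direction, called 0 without the block and 4 with it: interferon response, PPAR and fatty acid oxidation targets, cholesterol synthesis and heat shock.

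Named genes followed a rule fixed before the data were examined. Part (a) takes the 8 higher and 8 lower genes with the largest change among those with adjusted p under 0.05, a mean of at least 50 in 1 group and no overlap of the groups, without unnamed predictions and small RNA genes. Part (b) takes up to 4 members of each list with the smallest p, and always Il6, Tnf, Il1b, Il12b, Il10, Nfkbia, Ppara, Ppard, Pparg, Cpt1a, Pdk4, Plin2 and Angptl4. Only some of the genes of both parts are described. As part (a) found 0 genes without the block, it was applied to the block fit.

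The scripts were tested on simulated counts of the 10999 genes in the design of the treated against vehicle comparison, with the replicate differences kept and 200 genes changed by known folds. The 200 changed genes were drawn from genes with a mean of at least 50, so recovery of lower genes was not tested. limma without the block recovered 0% of 1.5-fold, 49.3% of 2-fold and 93.9% of 4-fold changes with 0 false calls. With the block it recovered 64.2%, 98.5% and 100% with 19 false calls. Those stood beside 43, 66 and 66 recovered genes, a larger false share than the threshold of 0.05 aims at. Of 20 unchanged simulated lists, 0 had a camera p under 0.05 in the block design. Apart from the kept replicate differences, genes were simulated independently of each other. The simulation therefore cannot test the preset correlation on lists whose genes vary together. In the data the estimated correlation without the block reached 0.74, for the interferon response list. The alternatives were total-sum, upper-quartile and quantile scaling, pseudocounts of 0.5 and 8, no filter, a minimum mean of 50, limma without trend or with sample weights, edgeR, DESeq2, the block and leaving out each library. The fits that leave out a single library had no block, so the replicate numbers were unbalanced between the groups. Replicate differences therefore enter the treatment difference of those fits.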

Results

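Macrophages were taken from the peritoneum of male BALB/c mice 4 days after an injection of thioglycollate medium, an irritant that draws monocytes and macrophages into the cavity. The cells were stimulated with lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that switches on inflammatory genes through Toll-like receptor 4. The question was whether 10(Z)-hexadecenoic acid, a monounsaturated fatty acid made by bacteria, lowers that inflammatory response. RNA sequencing of 3 libraries from cells in plain medium (vehicle) was compared with 3 libraries from cells in medium with 200 µM of the fatty acid (treated). No library from unstimulated cells was analysed here, so each value compares LPS-stimulated cells with LPS-stimulated cells. The timing and dose of LPS and the hours of exposure are not given in the sources used here.

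Each library held between 4291779 and 5963153 reads assigned to genes, and 10999 genes had a mean of at least 10 normalized reads. The largest part of the variance between the libraries followed the replicate number more than the treatment. The first principal component carried 40.8% of the variance and placed both libraries of replicate 1 lowest and both of replicate 2 highest. On it each treated library also lay below the vehicle library of its number: -23.3 and -37.6 for replicate 1, 32.8 and 16.4 for replicate 2, and 9.98 and 1.65 for replicate 3 (vehicle first). The second component, with 26.6%, placed each treated library above the vehicle library of its number: -27.0 and 23.7 for replicate 1, -0.41 and 25.9 for replicate 2, and -13.5 and -8.69 for replicate 3. Same-numbered libraries deviated together from their group means, so the values of a fit with the replicate number as a block are printed beside those of the fit without it wherever a call changes.

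**Figure D1:**
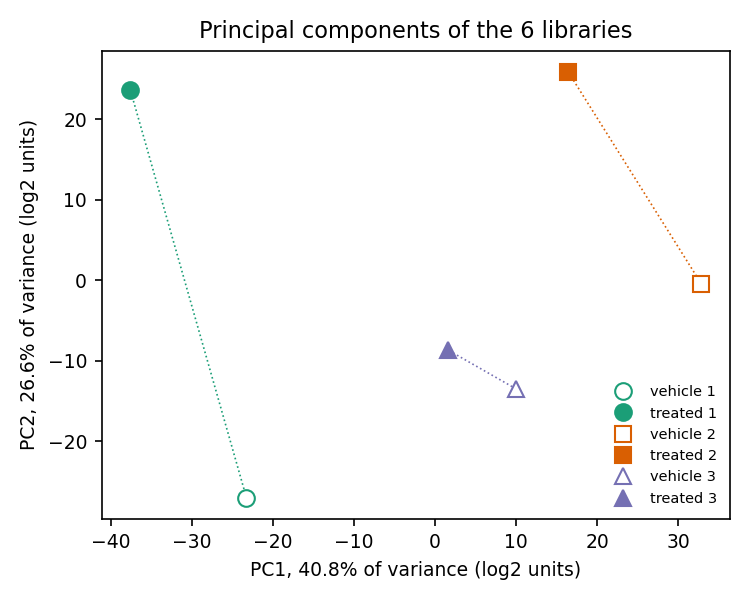
First and second principal components (log2 units) of 10999 genes in 6 libraries, with open symbols for vehicle, filled symbols for treated and a dotted line joining the libraries of 1 replicate number. The 2 libraries of replicate 3 lie closest together, at -13.5 and -8.69 on the second component.

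In all 3 pairs of libraries, treated cells had a higher median for the list of fatty acid oxidation genes and targets of the peroxisome proliferator-activated receptors (PPARs) and lower medians for the inflammatory cytokine and chemokine lists. These lists passed with the preset correlation and not with an estimated correlation (adjusted p = 0.388, 0.202 and 0.202). The estimated form has few degrees of freedom with 3 libraries per group, so that miss alone does not show that correlation made the calls. With all 6 libraries, limma called single genes only when the pairs were modelled; without treated replicate 3 it called 15 higher and 12 lower without the block. DESeq2 also called the 6 genes named next without the block. With the replicate block, the lipid droplet coat gene Plin2 rose 2.91-fold and Cpt1a, the enzyme that admits long-chain fatty acids to mitochondrial oxidation, rose 1.82-fold. In the same fit the cytokine genes Il6 and Tnf fell, with log2 changes of -2.27 and -1.08, as did the monocyte chemokine genes Ccl2 and Ccl7, with -1.32 and -1.45. Without the block, limma called 0 genes higher and 0 lower at an adjusted p of 0.05; 769 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.422. Without the block edgeR called 0 genes as well (805 at an unadjusted p under 0.05), and DESeq2 called 15 higher and 16 lower. With the block, limma called 17 higher and 39 lower, of which 6 and 15 changed at least 2-fold. The block counts depended on which pairs were included: 11 genes were called without replicate 1, 0 without replicate 2 and 650 without replicate 3. Restricting the block fit to genes with a mean of at least 50 left 2 calls, limma without a trend left 0, and total-sum scaling gave 19 higher and 21 lower. All 56 genes called with the block moved the same way in all 3 pairs, which a paired fit favours, and for 35 of them the groups did not overlap. Across all genes tested, 36.1% moved the same way in all pairs, where chance gives 25%. For 12.3% the groups did not overlap, where chance gives 10% if the 6 libraries are interchangeable. Same-numbered libraries deviated together, so 10% is not an exact baseline here.

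No gene met the rule for the largest changes without the block. In the block fit, a choice made after seeing this, 31 genes met it, 14 higher and 17 lower, and some of those with the largest changes are described here. Plin2 (ENSMUSG00000028494, chromosome 4, 86648386 to 86670060) went from 1777 ± 228 to 5305 ± 1709 normalized reads (mean ± SD, n = 3 per group throughout), a log2 change of 1.54 with a standard error of 0.11 and a limma adjusted p of 0.00356 with the block (0.422 without). Fos, an immediate early transcription factor gene, rose by 1.56 on the log2 scale, from 62.6 ± 20.8 to 184 ± 59.2 normalized reads. The calcium channel gene Cacna1d (1.38), the protein kinase A regulatory subunit gene Prkar2b (0.89), Cpt1a (0.86), the sphingomyelin synthase gene Sgms1 (0.85) and the matrix protein gene Tgfbi (0.83) were also higher, with block adjusted p between 0.0249 and 0.0464.

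Among the lower genes, Hdc, which encodes the enzyme that makes histamine, had the largest decrease among the genes that met the rule, which asks for a mean of at least 50, a log2 change of -2.76, from 83.4 ± 50.1 to 11.5 ± 7.08 normalized reads. Hdc is also the only tested member of the mast cell and eosinophil list, whose summed reads were lower in every pair (155, 111 and 101 in vehicle, 16.2, 21.7 and 65.3 in treated). Hdc itself made up 139.9, 65.6 and 44.7 of the vehicle sums. The mast cell protease genes Tpsab1 and Tpsb2 averaged 7.31 and 4.53 normalized reads in vehicle and 3.19 and 1.97 in treated libraries. Both had 0 reads in vehicle replicate 1, where Hdc was highest and from which it fell most (log2 change of -3.57 in pair 1). The lower Hdc values therefore do not show a loss of mast cells. Ch25h, which encodes cholesterol 25-hydroxylase, an interferon-inducible enzyme, fell 5.19-fold, from 100.3 ± 17.6 to 19.6 ± 8.27. F3, the gene of tissue factor, the starter of coagulation, fell 4.53-fold, and Plbd1, a phospholipase-like gene, fell 3.66-fold. Il6, Ccl7, Ccl2 and Tnf complete the lower genes. Block adjusted p for these 8 genes lay between 0.00873 and 0.0456 in limma. DESeq2 with the block did not call Plbd1 (adjusted p = 0.0976), while edgeR with the block did (0.0329). The pair changes of Plbd1 were -2.80, -2.06 and -0.75. Exons of Cacna1d, Sgms1 and Ch25h share positions with Chdh, 2700046G09Rik and Gm26902 on the opposite strand, and the strand setting of the counting is not given in the sources used here, so reads of these partners cannot be told apart.

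Of the 21 tested genes of inflammatory cytokines and mediators, 19 had lower values in treated cells, with a median log2 change of -0.84 and pair medians of -1.14, -0.77 and -0.47. The list was lower than the other genes in limma's camera test with the preset correlation (adjusted p = 1.06e-06), but not with an estimated correlation (adjusted p = 0.202). Over all genes tested limma called 0 members without the block and 3 with it, while edgeR called 0 and 5 and DESeq2 3 and 4. Adjusted over the list alone the limma counts were 8 lower and 0 higher without the block and 13 lower and 2 higher with it. Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), a pyrogenic cytokine gene, went from 1302 ± 190.2 to 305 ± 191 normalized reads, a log2 change of -2.27 with a standard error of 0.30 and an adjusted p of 0.0257 in the limma block fit (0.535 without). Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) went from 2098 ± 312 to 1023 ± 342, with a block adjusted p of 0.0435. Il1b, the gene of interleukin-1 beta, averaged 15956 ± 5200.0 in vehicle and 5349.5 ± 5175 in treated libraries, and did not pass in limma with the block (adjusted p = 0.0725). Its pair changes were -3.14, -2.27 and -0.44, and without treated replicate 3 it passed even without the block. Exons of Il1b share positions with the antisense gene Il1bos. Ptgs2, the inducible cyclooxygenase gene (5.29-fold lower, block adjusted p = 0.064), Il12a (2.83-fold lower, 0.0614) and Il12b (2.27-fold lower, 0.0576) missed the limma threshold as well, though edgeR with the block called both Il12 genes. DESeq2 called Il12a without the block (adjusted p = 0.033) and not with it (0.207). Saa3, an acute-phase gene, was one of the 2 members with a higher value (8029 ± 383 against 15753 ± 8379, block adjusted p = 0.253), with pair changes of 1.56, 1.14 and -0.32. Il10, an anti-inflammatory cytokine gene, had 4 reads over the vehicle libraries and 15 over the treated ones, a ratio of 3.11 with an exact 95% counting interval of 0.989 to 12.9. The spread between libraries is not part of that interval.

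All 13 tested chemokine genes had lower values, with a median log2 change of -0.79. Mesothelial and fibroblast markers were lower in the same pairs, with pair medians of -0.39, -0.58 and -0.54 (adjusted p = 0.803 with an estimated correlation). The chemokine list passed with the preset correlation (camera adjusted p = 1.06e-06, and 0.202 with an estimated correlation). With the block limma called 3 members over all genes tested and 11 adjusted over the list alone; without it the counts were 0 and 3. Over all genes tested DESeq2 called 3 without the block and 6 with it, and edgeR 0 and 4. Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453) fell from 5656 ± 2092 to 2234 ± 733 normalized reads (block adjusted p = 0.00873) and its neighbour Ccl7 from 1182 ± 416 to 441 ± 168. Ccl17, which attracts T cells, fell from 24.3 ± 16.3 to 2.87 ± 2.72 (block adjusted p = 0.0464). Ccl22 had 327 ± 90.4 and 117 ± 117 and did not pass (0.0757).

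**Figure D2:**
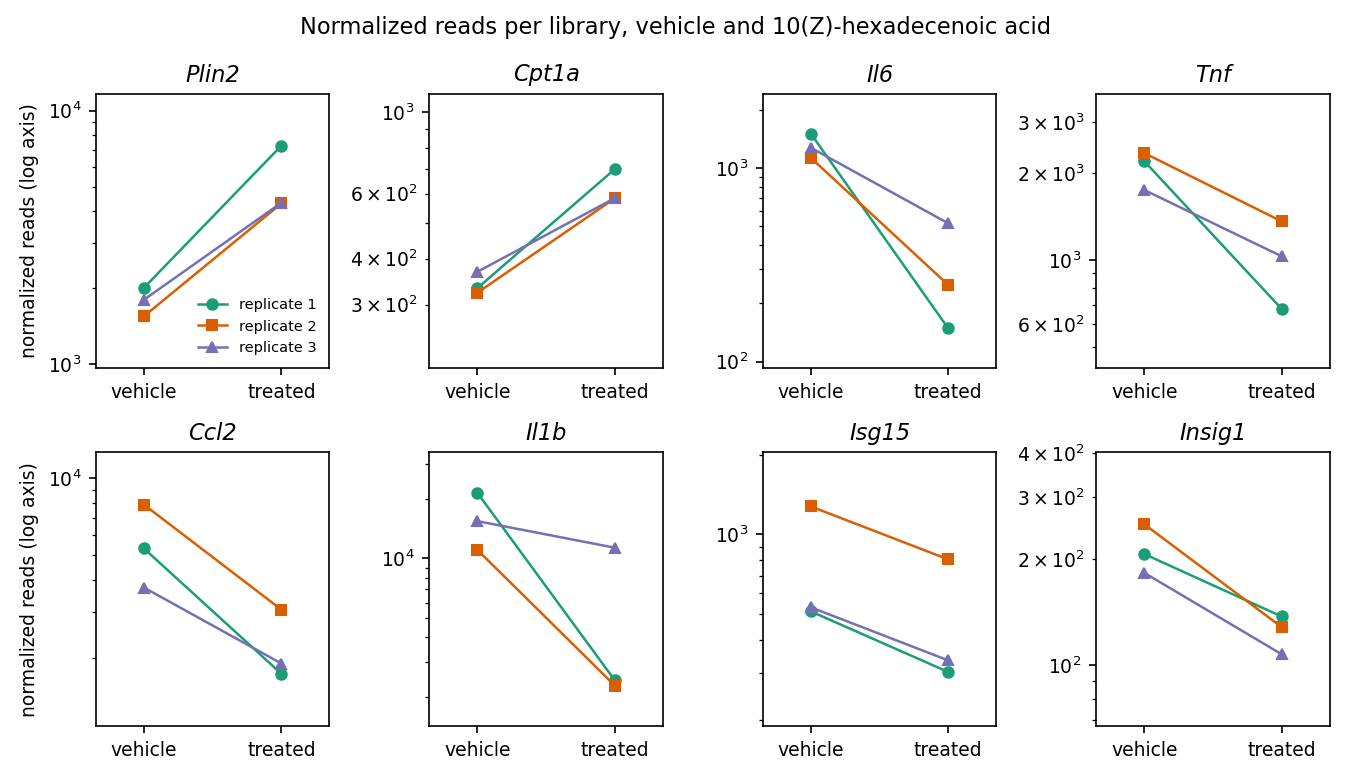
Normalized reads (log axis) of 8 genes in each library, vehicle at left and treated at right, with 1 line per replicate number. Each gene has the same direction in all 3 replicates, and Il1b in replicate 3 falls least, from 15412 to 11325.

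Genes of the NF-kB pathway, the transcription factor family downstream of Toll-like receptors, had a median log2 change of -0.25 over 22 tested members, 14 lower and 8 higher. The list passed with the preset correlation (camera adjusted p = 0.00117) and not with an estimated correlation (adjusted p = 0.406). The subunit genes Nfkb1 and Nfkb2 fell 1.59-fold and 1.65-fold with the block (adjusted p = 0.0257 and 0.0258) and were the 2 members limma called over all genes tested; 7 were called adjusted over the list alone, against 2 without the block. Without the block limma and edgeR called 0 members over all genes tested and DESeq2 1, Nfkb2. Exons of Nfkb2 share positions with Psd on the opposite strand. Nfkbia, the inhibitor gene induced by NF-kB, had 941 ± 135 and 992 ± 118 normalized reads, a log2 difference of 0.08 with a standard error of 0.07 in the block fit. The pair medians of the list were -0.48, -0.25 and -0.03.

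Feedback inhibitors of inflammation had a median log2 change of -0.54, with 12 of 17 tested members lower (camera adjusted p = 0.0028; adjusted p = 0.435 with an estimated correlation). Their pair medians were -1.03, -0.52 and -0.04. No member was called over all genes tested in limma, edgeR or DESeq2 with or without the block, and adjusted over the list alone 1 was lower without the block and 8 lower and 2 higher with it. Cish, a STAT5 target that restrains cytokine signalling, had 248 ± 149.8 and 50.2 ± 37.7 normalized reads, with pair changes of -3.91, -2.43 and -0.76. Tsc22d3, the glucocorticoid-induced leucine zipper gene, moved the other way, from 122 ± 40.5 to 537 ± 342, with pair changes of 3.13, 2.26 and 0.16 (block adjusted p = 0.0991).

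Interferon-response genes varied more with the replicate number than with treatment. Their summed normalized reads were 21156, 59036 and 31250.3 in vehicle replicates 1 to 3 and 16457, 46753 and 22956 in the treated ones, and summed T and NK cell marker reads were in the same order in both groups (14.3, 47.7 and 43.6 in vehicle, 8.66, 40.9 and 32.7 in treated). So were those of mesothelial and fibroblast markers (430.5, 1364 and 944 in vehicle, 325, 835 and 614 in treated). Of 31 tested members 28 had lower values, with a median log2 change of -0.42 and pair medians of -0.38, -0.22 and -0.49. The list passed with the preset correlation (camera adjusted p = 0.00237, and 6.52e-20 with the block), but not with an estimated correlation (adjusted p = 0.933, and 0.302 with the block). It also did not pass without vehicle replicate 2 (adjusted p = 0.878), without treated replicate 1 (0.537) or without treated replicate 3 (0.125). Its median was -0.01 without vehicle replicate 2, -0.05 without treated replicate 1, -0.73 without vehicle replicate 1 and -0.83 without treated replicate 2. These fits had no block, so leaving out a single library let the large replicate differences of this list into the treatment difference. They therefore cannot tell an unstable treatment difference from the replicate differences. Over all genes tested limma called 0 members without the block and 6 with it, edgeR 0 and 8, and DESeq2 0 and 6; adjusted over the list alone the limma counts were 0 and 24. Isg15, a ubiquitin-like antiviral gene (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), went from 773 ± 435 to 481 ± 281 normalized reads; its standard error on the log2 scale was 0.45 without the block and 0.08 with it, where the adjusted p was 0.0249. Oasl1 fell 1.63-fold and Cmpk2 1.84-fold in the block fit (adjusted p = 0.0249 and 0.0257), and exons of Oasl1 share positions with Gm13822 on the opposite strand.

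PPAR targets and fatty acid oxidation genes had higher values in 24 of 27 tested members, with a median log2 change of 0.22 and pair medians of 0.43, 0.17 and 0.25. It was the only list called higher among the 26 tested (camera adjusted p = 2.21e-07; adjusted p = 0.388 with an estimated correlation). Over all genes tested limma called Plin2 and Cpt1a with the block and 0 members without it, edgeR 4 and 0, and DESeq2 2 in either fit; adjusted over the list alone in limma 8 were higher with the block and 2 without. Cpt1a (ENSMUSG00000024900, chromosome 19, 3322334 to 3385733) went from 341 ± 23.8 to 622 ± 67.1 normalized reads, with pair changes of 1.07, 0.85 and 0.66 and a block adjusted p of 0.0249. The mitochondrial uncoupling protein gene Ucp2 had 931 ± 87.2 and 1317 ± 232 (block adjusted p = 0.0641), and the fatty acid isomerase gene Eci2 66.5 ± 11.5 and 99.7 ± 7.73 (0.105); their exons share positions with Dnajb13 and Gm16984 on the opposite strand. Angptl4, a secreted lipase inhibitor gene induced by PPARs, had 1 read over the vehicle libraries and 20 over the treated ones, a ratio of 16.6 with an exact 95% counting interval of 2.65 to 687. That interval leaves out the spread between libraries, which had 0, 0 and 1 reads in vehicle and 6, 9 and 5 in treated replicates 1 to 3. Pdk4 had 1 read in all libraries together.

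The genes of the PPARs themselves did not pass in limma, edgeR or DESeq2. Ppara had 0 reads in every library, which allows up to 3 reads per library. Pparg had 15.4 ± 4.74 and 37.5 ± 17.5 normalized reads with no overlap between the groups (block adjusted p = 0.108), and Ppard 172 ± 14.2 and 145 ± 42.4 (0.539). The list of nuclear receptors and coregulators had a median log2 change of 0.01 over 16 members (camera adjusted p = 0.423), and targets of the liver X receptors, oxysterol sensors, had a median of 0.05 over 15 (adjusted p = 0.894), a list whose mean was -0.01 and whose test pointed down.

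Cholesterol synthesis genes were lower in 20 of 24 tested members, with a median log2 change of -0.26 and pair medians of -0.10, -0.28 and -0.31 (camera adjusted p = 0.00024; adjusted p = 0.435 with an estimated correlation). Insig1, a sterol-responsive regulator gene (ENSMUSG00000045294, chromosome 5, 28071363 to 28078662), fell from 214 ± 34.7 to 124 ± 15.4 normalized reads and was the only member limma called over all genes tested with the block (adjusted p = 0.0435), where edgeR called 2 and DESeq2 0; 3 were called adjusted over the list alone, against 2 without the block. Cyp51, a sterol demethylase gene whose exons share positions with Akap9, had 112 ± 7.96 and 71.6 ± 8.32 (block adjusted p = 0.0911). Fatty acid synthesis and desaturation genes had a median of -0.05 over 15 members (camera adjusted p = 0.702).

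Unfolded protein and integrated stress response genes had a median log2 change of -0.22, with 23 of 27 lower (camera adjusted p = 0.00237; adjusted p = 0.382 with an estimated correlation) and a pair median of -0.01 in pair 3. Their median was -0.15 without vehicle replicate 2 and -0.13 without treated replicate 1. Heat shock genes had a median of -0.22 with 12 of 13 lower (adjusted p = 0.00117; adjusted p = 0.435 with an estimated correlation); the median was -0.14 without vehicle replicate 2. The heat shock protein 70 gene Hspa1b had 30.8 ± 33.6 and 4.87 ± 2.35 normalized reads, and whether reads of its close paralog Hspa1a were told apart was not tested. Ribosomal protein genes had a median of -0.12 with 29 of 30 lower (adjusted p = 0.00028; adjusted p = 0.803 with an estimated correlation), and did not pass without treated replicate 3 (adjusted p = 0.103), where the median was -0.07, as it was without vehicle replicate 1. Glycolysis and hypoxia genes had a median of -0.18 with 20 of 26 lower and an adjusted p of 0.0499, or 0.933 with an estimated correlation. Their median was 0.03 without treated replicate 1, -0.07 without vehicle replicate 2, -0.10 without vehicle replicate 3, -0.35 without vehicle replicate 1 and -0.34 without treated replicate 3, and the list did not pass without vehicle replicate 2 (adjusted p = 0.645) or vehicle replicate 3 (0.628). All fits of these lists with a single library left out had no block, so replicate differences enter them. The glucose transporter gene Slc2a1 was 1.68-fold lower and the glycolytic regulator gene Pfkfb3 1.41-fold higher, and neither passed in limma, though DESeq2 with the block called Slc2a1 (adjusted p = 0.0296).

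Genes that mark macrophages did not move as a group. The macrophage identity list had a median log2 change of -0.08 over 23 members, a mean of 0.01 and a camera adjusted p of 0.733. Csf1r, the receptor gene of the macrophage growth factor, had 1988 ± 287 and 2403 ± 229.5 normalized reads (block adjusted p = 0.184). Among 10 tested genes of alternative activation (median -0.27, adjusted p = 0.923), the coagulation factor gene F13a1 rose 2.30-fold with the block (adjusted p = 0.0257) and the scavenger receptor gene Stab1 had 293 ± 29.5 and 430.2 ± 42.7 (0.0748). Antigen presentation genes had a median of -0.31 with 15 of 17 lower, and did not pass without the block (camera adjusted p = 0.14). They passed with it (adjusted p = 5.06e-05; adjusted p = 0.469 with an estimated correlation), and without the block after total-sum scaling, with no filter, in DESeq2, without vehicle replicate 1 (adjusted p = 0.00025, median -0.71) and without treated replicate 2 (0.0012, median -0.51). Their median was 0.10 without vehicle replicate 2 and 0.20 without treated replicate 1. Those fits had no block and unequal replicate numbers in the groups, so replicate differences enter these medians. Within the pairs the medians of antigen presentation genes were -0.41, -0.27 and -0.06. Cell cycle genes had a median of 0.06 (adjusted p = 0.702), while the proliferation marker gene Mki67 fell 1.43-fold with the block (0.0257). Lists of the NRF2 antioxidant response (median -0.11, adjusted p = 0.859), oxidative phosphorylation (-0.02, 0.733), inflammasome and innate sensors (-0.07, 0.34), lysosome (-0.04, 0.702) and apoptosis and p53 (0.03, 0.959, with a mean of -0.04) did not pass.

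Among markers of other cells, mesothelial and fibroblast genes were lower in 8 of 8 tested members, with a median log2 change of -0.50 and pair medians of -0.39, -0.58 and -0.54 (camera adjusted p = 0.0378; adjusted p = 0.803 with an estimated correlation). The collagen gene Col1a2 had 229.6 ± 121 and 139 ± 70.7 normalized reads and the proteoglycan gene Dcn 155 ± 42.3 and 114 ± 19.3. Neither passed in limma, while edgeR with the block called Col1a2 (adjusted p = 0.0441). Adjusted over the list alone limma called 4 members lower with the block and 0 without it. The list did not pass without vehicle replicate 2 (adjusted p = 0.645), vehicle replicate 3 (0.0651), treated replicate 1 (0.42) or treated replicate 3 (0.123). Its median was -1.23 without vehicle replicate 1, -0.13 without vehicle replicate 2, -0.19 without treated replicate 1 and -0.89 without treated replicate 2. No block was used in those fits either, so replicate differences enter them. B cell markers had a median of -0.22 over 7 members (adjusted p = 0.273) and dendritic cell markers 0.11 over 7 (0.894, with a mean of -0.01). The lists of neutrophil, T and NK cell, mast cell and eosinophil, resident peritoneal macrophage and mitochondrially encoded genes had fewer than 5 tested members and were not tested. Prg4, a marker of resident peritoneal macrophages, had 23.1 ± 6.77 and 51.5 ± 8.32 normalized reads, without overlap between the groups (limma block adjusted p = 0.0757). Exons of Cish, Slc2a1, Stab1, Csf1r and Prg4 share positions with Gm17040 and Gm17041, Gm12868, Nt5dc2, Hmgxb3 and Tpr on the opposite strand.

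**Figure D3:**
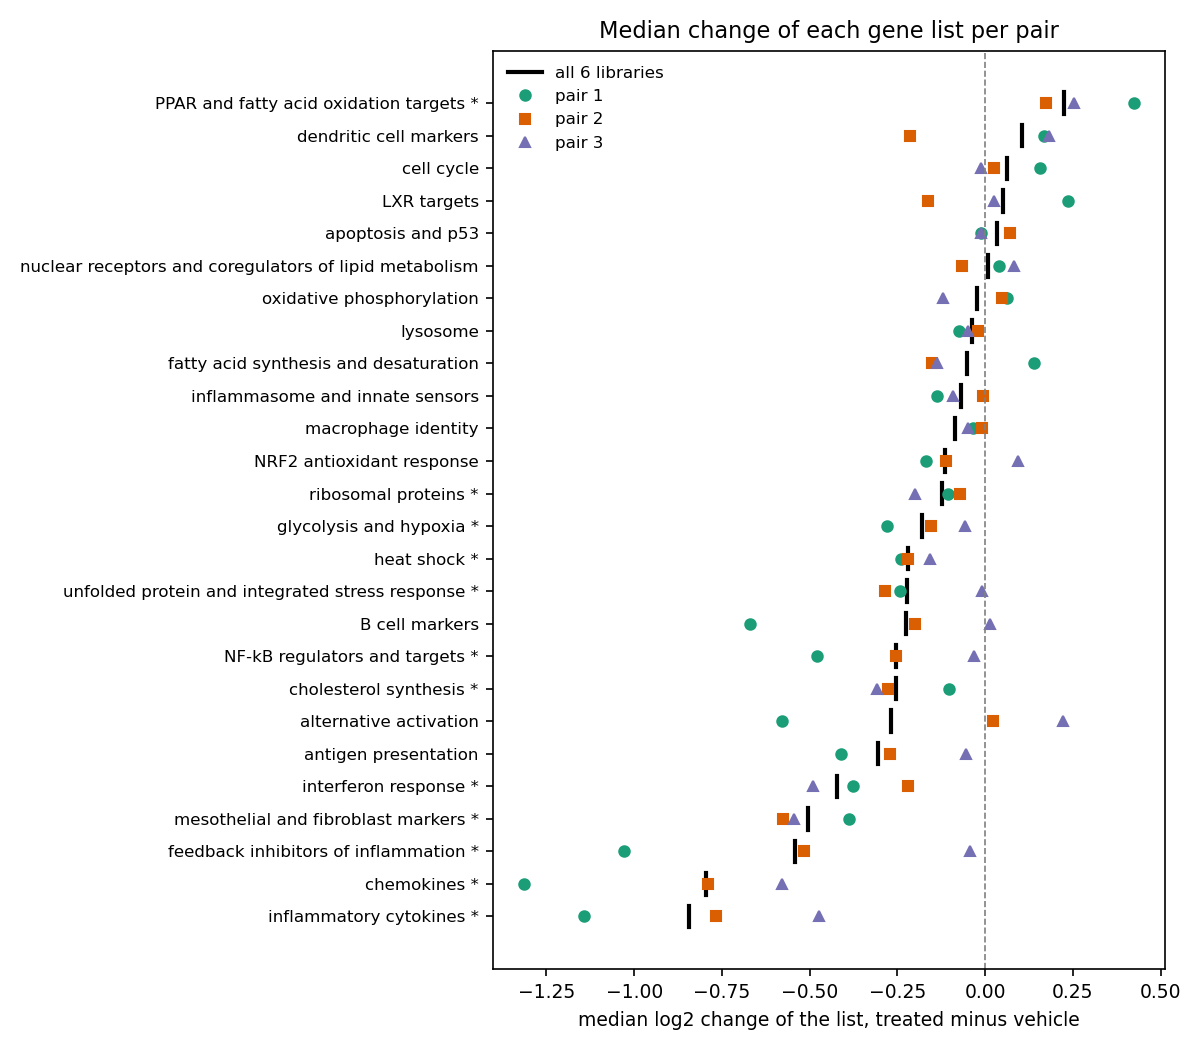
Median log2 change, treated minus vehicle, of each of 26 gene lists over all 6 libraries (black bars) and within each pair (symbols), with an asterisk on the 12 lists called by camera with the preset correlation and without the block. The chemokine and cytokine lists have the lowest medians, -0.79 and -0.84, and the PPAR and fatty acid oxidation list the highest, 0.22.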

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

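The block fits of edgeR and DESeq2, every alternative run within the block fit, and the fits without a pair were chosen after seeing the data. Without the block, the counts of 0 genes higher and lower held under each scaling, both pseudocounts, both filters, limma without trend, sample weights and edgeR. DESeq2 gave 15 higher and 16 lower (12 and 14 at least 2-fold). Leaving out 1 library gave 0 to 15 higher, 0 to 12 lower, and 0 to 14 and 0 to 12 at least 2-fold; the upper values came without treated replicate 3, and without any other library the counts were 0. The replicate block gave 17 higher and 39 lower (6 and 15 at least 2-fold), edgeR with the block 48 and 73 (22 and 31), and DESeq2 with the block 27 and 50 (13 and 23). All 56 limma block genes were among the edgeR block calls and 42 among those of DESeq2 with the block.

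Within the block fit, higher and lower counts were 187 and 260 with no filter, 1 and 1 at a minimum mean of 50, 0 and 0 without trend, and 103 and 165 with sample weights; lower counts were 21 with total-sum scaling and 21 with quantile normalization. Leaving out a pair gave 0 to 282 higher and 0 to 368 lower, the lowest without replicate 2 and the highest without replicate 3, where all 56 genes were called again; without replicate 1, 7 of the 56 were called. The cause of these differences was not tested, except that fewer libraries leave fewer degrees of freedom. At this depth and spread, the simulated 1.5-fold changes were not recovered without the block.

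The number of lists called by camera with the preset correlation stayed between 9 and 14 of 26 under the other planned settings and left-out libraries, and 13 with the replicate block. When a pair was left out of the block fit, the number was 13 to 15. With the correlation estimated per list, and with both forms of fry, it was 0 without the block. With the block it was 0 with an estimated correlation and 0 with directional fry, but 4 with mixed fry. The block ended no list call of the fit without it and added antigen presentation. Glycolysis and hypoxia missed the threshold with quantile normalization (adjusted p = 0.275), a pseudocount of 0.5 (0.0509), a minimum mean of 50 (0.0856), limma without trend (0.0763) and edgeR (0.0816). Interferon response missed it with sample weights (0.103), and mesothelial and fibroblast markers at a minimum mean of 50 (0.135) and with sample weights (0.0574). The block changed no other list call by camera. In DESeq2 it ended the call of Il12a.

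No called list or gene changed direction under another scaling. Lists near 0 did. Total-sum scaling raised the median of all genes by 0.0623 on the log2 scale, and that shift turned the medians of fatty acid synthesis and desaturation (0.012), oxidative phosphorylation (0.0395) and lysosome (0.0261) positive, and quantile normalization turned lysosome to 0.0458, of which the cause was not tested. Nuclear receptors and coregulators of lipid metabolism turned to -0.0061 at a minimum mean of 50 and -0.0322 with sample weights. With 1 library left out, medians ranged from -0.0481 to 0.0484 for nuclear receptors, -0.0395 to 0.116 for LXR targets, -0.0755 to 0.0212 for fatty acid synthesis, -0.140 to 0.0321 for NRF2, -0.351 to 0.0333 for glycolysis and hypoxia, and -0.118 to 0.0837 for oxidative phosphorylation. They ranged from -0.123 to 0.0040 for macrophage identity, -0.711 to 0.204 for antigen presentation, -0.0245 to 0.191 for cell cycle, -0.0720 to 0.0793 for apoptosis and p53, -0.0710 to 0.0175 for lysosome, -0.480 to 0.166 for B cell markers and -0.0939 to 0.222 for dendritic cell markers. Those fits had no block, so replicate differences enter these ranges. The change of Nfkbia ranged from -0.0158 to 0.19. The change of Arg1, -0.68, turned to 0.245 in edgeR and 0.244 in DESeq2, and ranged from -2.03 without treated replicate 3 to 0.314 without treated replicate 1. With 1 library left out, Nos2 (-0.83) ranged from -2.20 without vehicle replicate 1 to 0.62 without treated replicate 1, and passed only in the fits with the block. Ifng (-0.19) turned to 0.0355 with sample weights and ranged from -1.57 without vehicle replicate 1 to 1.38 without vehicle replicate 2.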

Other observations

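The tests of RNA mixing, of shrinkage in picked genes and of lymphocytes were chosen after the results they bear on were seen. The glucocorticoid hypothesis was raised by the genes of the pattern; its 17 further targets were listed before their values were examined. The genes named in this part were chosen after their values were seen, apart from Ptgs2, Lck, Plin2, F3, Il6 and Ch25h.

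A group of genes changed at least 2-fold in pairs 1 and 2 and mostly less in pair 3. Among genes with a mean of at least 50 normalized reads, 90 changed at least 2-fold in the same direction in pairs 1 and 2, 38 higher and 52 lower. In pair 3, 66 of them kept their direction, and 4 (Plin2, F3, Il6 and Ch25h) again changed at least 2-fold in it. Higher genes included Hp (haptoglobin), with 759, 533 and 1102 normalized reads in vehicle replicates 1 to 3 and 6609, 2936 and 1120.2 in the treated ones. Dusp1, a phosphatase gene that limits MAP kinase signalling, had 110.0, 123 and 111 in vehicle and 672, 581 and 111 in treated libraries, and Fkbp5, a cochaperone gene of the glucocorticoid receptor, had 63.4, 38.8 and 61.0 against 282, 154 and 51.6. Exons of Dusp1 share positions with Ergic1 on the opposite strand. Lower genes included Clec7a, the beta-glucan receptor gene, with 1431, 762 and 1891 against 82.3, 78.6 and 1771, and Ptgs2, with 5264, 7108 and 6260.3 against 374, 1106 and 3827. Irf4, a transcription factor gene, had 151, 52.7 and 58.8 against 16.2, 23.3 and 50.7, while the arginase gene Arg1, with 134, 319.9 and 798 against 49.8, 125 and 1299.9, turned direction in pair 3. So did ENSMUSG00000093077, with 13625, 7083 and 623 against 644, 261 and 5913, and Rmrp, with 5568, 4316 and 2345 against 2154, 1329 and 3110. For these 2 genes vehicle replicate 3 also lay below the other vehicle libraries, so the pattern was not confined to treated replicate 3. The cause was not tested. Across 7636 genes the pair changes correlated at 0.64 for pairs 1 and 2, 0.22 for pairs 1 and 3 and 0.20 for pairs 2 and 3 (Pearson, over genes, which are not independent replicates).

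Shrinkage of picked genes would act alike on pairs left out of the picking. The 287 genes that changed at least 2-fold in pair 1 kept a median share of 0.524 of their change in pair 2 and 0.117 in pair 3, a difference of 0.407 (95% bootstrap interval over genes 0.349 to 0.443), so picking alone does not account for the pattern. Vehicle RNA mixed into treated library 3 would pull every change there towards 0. The PPAR and fatty acid oxidation list kept 62.7% of its mean change in pair 3 (95% bootstrap interval over genes 24.7 to 130, and 19.7 to 170.1 without the 2 members that are among the 90 genes), above the median of 16.4% for the 90 genes, and the interferon list had a larger median change in pair 3 (-0.49) than in pairs 1 and 2 (-0.38 and -0.22). These values argue against mixing as the whole cause but do not exclude it. The 90 genes were picked on pairs 1 and 2, which lowers their share in pair 3, while the lists were not picked. Computed as for the PPAR list, the share of the 90 genes was 12.2%. The intervals are over genes and not over libraries. A hypothesis that stays open is that treated libraries 1 and 2 carried a glucocorticoid-type response that treated library 3 may have lacked: of 17 further glucocorticoid targets 11 were tested, and their median change stood at percentile 98.9 in pair 1, 98.6 in pair 2 and 89.8 in pair 3 of 10000 random lists matched on expression. In pair 3 they did not reach percentile 95. Of the 11, 7, 8 and 9 were above 0 in pairs 1, 2 and 3, so the count above 0 was not higher in pairs 1 and 2, and the 8 targets among the 90 genes had medians of 2.02, 1.75 and 0.01. The difference between the pairs was not tested, and no library with a glucocorticoid was analysed, so the source of such a response is not known.

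The second pattern is that same-numbered libraries of the 2 groups deviated together. Depth was argued against: with all libraries thinned to 4291779 gene reads, the lowest same-number correlation was still 0.249. Nos2, the inducible nitric oxide synthase gene, had 386, 12069 and 3796 normalized reads in vehicle and 198, 7934 and 2013 in treated libraries. A hypothesis that is left open is a different number of lymphocytes in the plated cells. The order of the libraries by T and NK marker reads equalled that by the interferon list in 2 of 2 groups, but theirs was 1 of 6 lists among 29 with that order, mesothelial and fibroblast markers being another, so the order does not single out lymphocytes. The interferon gamma gene Ifng had 0, 59 and 4 reads in vehicle and 0, 21 and 13 in treated libraries. These markers were few (8 to 51 reads per library over 16 genes, the most abundant being the kinase gene Lck), and the adherent cells had been washed. Separate animals, litters or days may differ in the same way, which was not tested.

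The number of genes past the threshold was also compared with other splits of the 6 libraries. Without the block the real split gave 0 genes and the highest of the other splits 0, so 10 of 10 splits gave as many. With the block the real split gave 56 genes, and among the 4 splits that part all 3 pairs the highest of the others gave 1; the real split was the 1 split with as many. With 10 and 4 splits no share under 0.05 can be reached.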
